A study of Mus musculus with 15 samples.

How the data were processed

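RNA from whole livers of 15 mice was measured on Affymetrix whole-transcript arrays, 1 array per mouse and 3 mice in each of 5 groups (WT with a floxed NEMO gene, Jnk1 KO, Jnk2 KO, NEMO/Jnk1 DKO and NEMO/Jnk2 DKO). The authors deposited log2 expression values normalized by RMA, per the submitters' processing notes, which give no version. That the logarithm has base 2 was inferred from the range of the values. The arrays were grouped by their labels, which give each mouse its own number and call all of them male. No pair of arrays was identical, and the Pearson correlation between 2 arrays lay between 0.975 and 0.995.

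Probe sets were joined to gene symbols with the platform's gene table. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed in it. Only those with 1 symbol were tested. For the 999 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene, which left 19938 genes. No further normalization was applied. The probe sets outside the gene table and those with several symbols were tested apart.

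The comparisons, their tests, 35 gene lists, the rule for named genes and the first set of alternatives were written down before the data were examined. Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 15 arrays with 1 mean per group, so that all groups share 1 estimate of the spread (10 residual and 3.75 prior degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p under 0.05, without a minimal fold change. Gene lists were tested with camera from limma at its preset correlation of 0.01 and adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Of the 668 symbols in the lists 597 were measured. The difference of the NEMO effects was tested as the contrast of (NEMO/Jnk1 DKO less Jnk1 KO) less (NEMO/Jnk2 DKO less Jnk2 KO). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

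Genes named in the text are Mapk8, Mapk9 and Ikbkg, and, per comparison, the 10 that rose and the 10 that fell most among those past the threshold whose arrays do not overlap between the groups compared. Provisional gene models, small RNA genes and olfactory receptors count in the totals but were not named. For a list described in the text, up to 4 members past the threshold with the largest change are named, or, where none passed, the 2 with the lowest p.

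Other settings chosen beforehand were a fit to only the arrays compared, an intensity trend with a robust prior, array weights, quantile normalization of the deposited values again, centring of each array on its median, and a filter on dim probe sets. The filter kept the 12589 genes above 4.09 (the 40th percentile of all values) in at least 3 arrays. Others were a minimal fold change of 1.5, every probe set tested, the replicate number as a block, the genes on the chromosomes of Mapk8 and Mapk9 left out, each array left out in turn, and the self-contained test fry for the lists. After seeing the data, 4 more were added: leaving out the 2 doubted arrays (8 residual and 5.05 prior degrees of freedom), a term for the sex read from Xist and the Y-linked genes, both together, and leaving out the 3 arrays with the female pattern. The comparison of all Jnk1-null with all Jnk2-null arrays was also added then.

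The pipeline was tested on simulated data with the spread of the arrays and known changes between NEMO/Jnk1 DKO and Jnk1 KO. As labelled, it recovered 46.3% of the changes of log2 0.5, 83.6% of those of 1 and 100% of those of 2, with 10 unchanged genes called. With the spread of the fit without the 2 doubted arrays these were 35.8%, 82.1% and 100%, with 6 unchanged genes called. The shifted list was called and 0 of the others. The simulated noise was independent, the changes were placed on random genes, and no simulated array carried the pattern of another group. As labelled, these shares therefore do not hold for the genes raised in the 2 doubted arrays. Between NEMO/Jnk1 DKO and Jnk1 KO, Ly6d was at 3.37 and Mmp12 at 2.83 (limma adjusted p = 0.962 for both).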

Results

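Gene expression was measured in whole livers of 15 mice on Affymetrix whole-transcript arrays, with 1 array per mouse and 3 mice in each of 5 groups, all 8 weeks old. The WT controls carried a floxed, intact NEMO gene. Jnk1 KO and Jnk2 KO mice lacked one of these stress-activated kinases in every cell. NEMO/Jnk1 DKO and NEMO/Jnk2 DKO mice also lacked NEMO, the regulatory subunit of the IkB kinase complex that activates NF-kB, in hepatocytes. Among these samples no group lacked NEMO alone, so the effect of its loss was read on the Jnk-null backgrounds. The values were log2 expression levels of 19938 genes, and the median over all probe sets lay between 4.26 and 4.38 in the 15 arrays, whose number limits the precision. Below, a fold change is given on the log2 scale with its standard error (SE) from the fit to all groups, and n = 3 arrays per group unless stated.

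Mapk9, which encodes JNK2, stood at 7.49 ± 0.13 (SD, n = 3) in WT, 7.55 ± 0.10 in Jnk1 KO and 7.56 ± 0.10 in NEMO/Jnk1 DKO, and at 2.92 ± 0.34 in Jnk2 KO and 2.66 ± 0.24 in NEMO/Jnk2 DKO. Mapk8, which encodes JNK1, stood at 7.01 ± 0.03 in WT, 6.73 ± 0.14 in Jnk2 KO and 6.75 ± 0.16 in NEMO/Jnk2 DKO, against 6.14 ± 0.09 in Jnk1 KO and 6.12 ± 0.35 in NEMO/Jnk1 DKO, where replicate 3 read 6.53. Ikbkg, which encodes NEMO, stood at 7.25 ± 0.14 in WT, 7.03 ± 0.25 in Jnk1 KO, 6.83 ± 0.52 in Jnk2 KO, 6.55 ± 0.34 in NEMO/Jnk1 DKO and 6.39 ± 0.08 in NEMO/Jnk2 DKO. Among the planned comparisons, the drop of Mapk9 passed the test in all 4 of Jnk2-null with Jnk2-intact groups (log2 difference from 4.57 to 4.90 in size). That of Mapk8 passed only between NEMO/Jnk1 DKO and WT (-0.88, SE 0.15, adjusted p = 0.0456), where the sex term described below left it at -0.64 (adjusted p = 0.457). Between all Jnk1-null and all Jnk2-null arrays, a comparison added later, Mapk8 also passed (-0.61, SE 0.10, limma adjusted p = 0.0135). Against WT, Ikbkg was at -0.70 (SE 0.22, adjusted p = 0.157) in NEMO/Jnk1 DKO and at -0.87 (SE 0.22, adjusted p = 0.0554) in NEMO/Jnk2 DKO. The files do not say which part of each gene its probe set covers, and liver cells other than hepatocytes keep NEMO, so a partial drop sets no limit on the deletion.

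In 2 arrays, expression did not follow the NEMO label. Ly6d read 10.1 in the array labelled Jnk1 KO replicate 1 and 9.70 in the array labelled Jnk2 KO replicate 3, against 4.67 to 5.35 in the other 7 arrays labelled NEMO-intact and 7.88 to 10.5 in the double knockouts. Mmp12, a macrophage elastase, read 8.66 and 8.20 in these arrays, against 3.69 to 4.88 in the other NEMO-intact arrays and 7.54 to 8.96 in the double knockouts. Ikbkg read 6.75 and 6.24 in these arrays, and 7.03 to 7.41 in the other NEMO-intact arrays. On the first principal component, which held 41.2% of the variance, they scored 33.8 and 19.3, the other NEMO-intact arrays from -26.2 to -15.5, and the double knockouts from 9.9 to 25.3. Their Jnk labels held, with Mapk8 at 6.06 in the array labelled Jnk1 KO replicate 1 and Mapk9 at 2.60 in the array labelled Jnk2 KO replicate 3. These are called the 2 doubted arrays. Each comparison is given as labelled and without them, a setting chosen after seeing the data. In that setting Jnk1 KO and Jnk2 KO have n = 2 arrays each. Because the doubted arrays were set aside by the same expression pattern that separates the double knockouts, the counts without them are not independent evidence of that pattern.

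All mice were labelled male. Xist, which female cells express from the inactive X chromosome, read 8.68 in the array labelled Jnk1 KO replicate 1 and 9.17 and 9.08 in the arrays labelled NEMO/Jnk1 DKO replicates 1 and 2, against 2.40 to 2.82 in the other 12 arrays. The mean of the Y-linked genes was 2.75 to 2.98 in those 3 arrays and 6.79 to 7.26 in the others. The female-biased liver genes lay on average 2.86 to 2.98 above WT in the 3 arrays and at most 0.67 above it in the others. A fit with this sex as a term was also chosen after seeing the data. The array labelled Jnk1 KO replicate 1 is also a doubted array, so with all arrays the term can take up part of its double-knockout pattern. With the doubted arrays left out, the term is set within NEMO/Jnk1 DKO, whose estimates then equal its replicate 3. Calls and p-values of NEMO/Jnk1 DKO from that fit thus rest on 1 array. Comparisons between groups without the female pattern change only in their estimated spread.

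**Figure D1:**
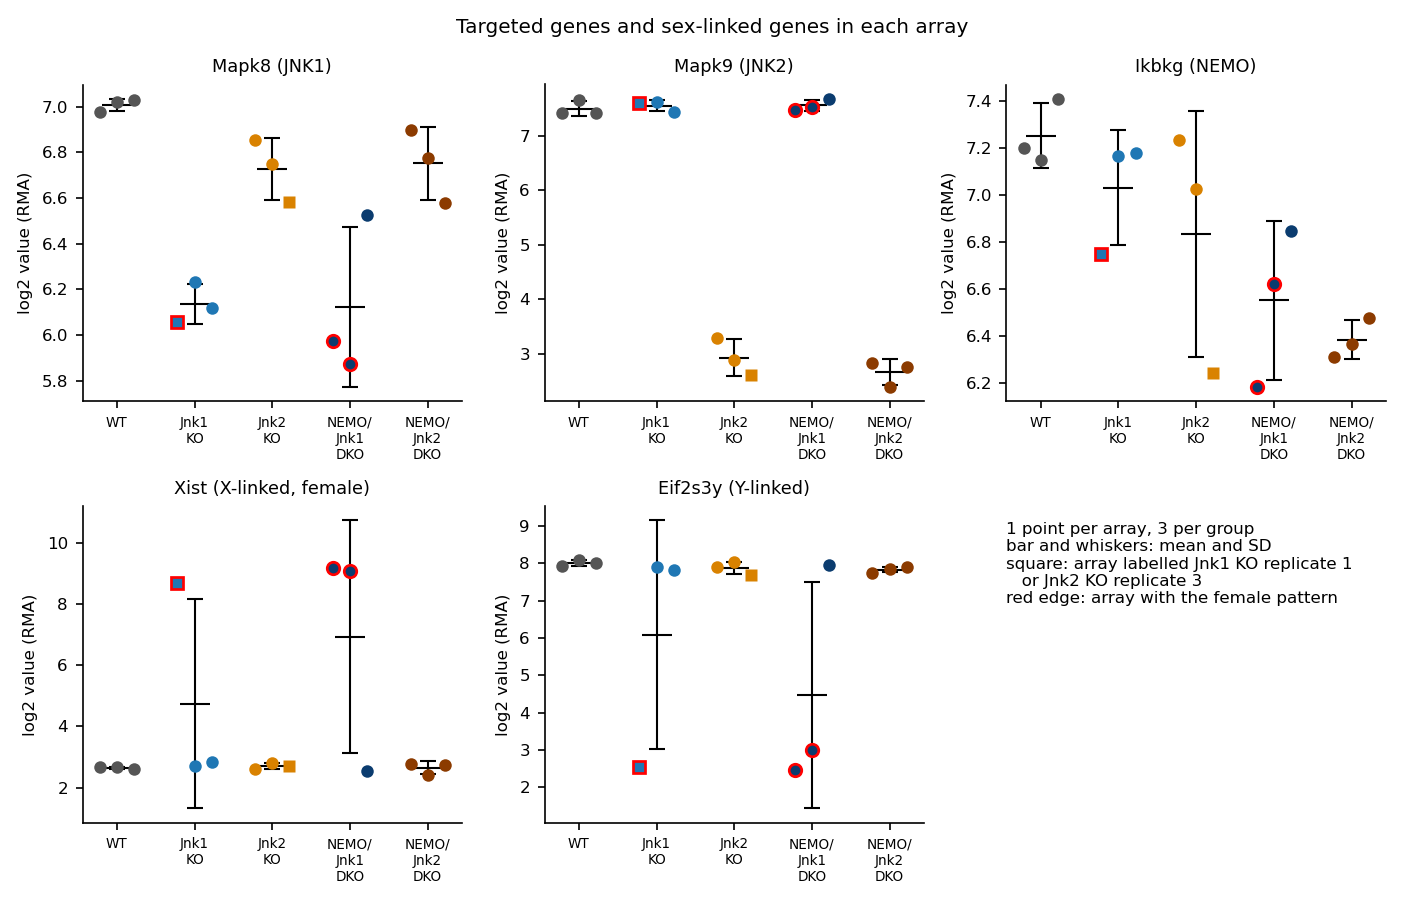
Log2 expression (RMA) of Mapk8, Mapk9, Ikbkg, Xist and the Y-linked gene Eif2s3y in each of the 15 arrays, by group, with the mean and SD of 3 arrays. Squares mark the arrays labelled Jnk1 KO replicate 1 and Jnk2 KO replicate 3, whose Ikbkg read 6.75 and 6.24, and red edges mark the 3 arrays with Xist at 8.68 to 9.17.

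Jnk1 KO differed from WT in 2 of the 19938 genes (limma, adjusted p under 0.05; 1113 at an unadjusted p under 0.05). Mme, the membrane peptidase neprilysin, rose by 3.78 (SE 0.32, adjusted p = 0.00028). Rps3a1, which encodes a ribosomal protein, fell by 1.46 (SE 0.16, adjusted p = 0.00256). With the 2 doubted arrays left out Asic5, an acid-sensing ion channel gene, passed as well (-1.90, SE 0.22, adjusted p = 0.00766), and both others kept their calls. These 3 genes lie on 1 chromosome, which is not that of Mapk8. With the sex term added to that setting 6 genes were called. As labelled and with only the arrays compared, neither of the 2 genes kept its call, and the count was 0 by limma (667 at an unadjusted p under 0.05). The cholesterol synthesis list, whose 17 measured members include the sterol enzymes Cyp51 (-0.57, SE 0.16, adjusted p = 0.86) and Sqle (-0.41, SE 0.15, adjusted p = 0.86), had a median of -0.35 (camera adjusted p = 4.2e-09; adjusted p = 0.659 with an estimated correlation), and of -0.33 without the doubted arrays (adjusted p = 6.26e-08; adjusted p = 0.754 with an estimated correlation). Fatty acid synthesis and lipid storage genes had a median of 0.08 (adjusted p = 0.123), with Cd36 at 1.05 and Dgat2 at -0.30, and of 0.10 without the doubted arrays (adjusted p = 0.000265; adjusted p = 0.72 with an estimated correlation).

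As labelled 10 lists differed between Jnk1 KO and WT by camera, 8 up and 2 down. Without the 2 doubted arrays the medians of all 5 given here changed sign. Of these lists 4 were then not called, and the extracellular matrix list was called in the opposite direction. The cell cycle list had a median of 0.73 (camera adjusted p = 1.63e-13; adjusted p = 0.659 with an estimated correlation), with Rrm2 at 0.89 and Melk at 0.49, and -0.045 without the doubted arrays (adjusted p = 0.736). Monocyte and macrophage markers had a median of 0.45 (adjusted p = 8.41e-07; adjusted p = 0.659 with an estimated correlation), with Adgre1 at 0.54 and Cd14 at 0.64, and -0.011 without them (adjusted p = 0.736). Extracellular matrix and stellate cell markers had a median of 0.28 (adjusted p = 0.00305; adjusted p = 0.659 with an estimated correlation), with Lox at 0.54 and Tgfb1 at 0.29, and turned to -0.18 without them (adjusted p = 0.0196; adjusted p = 0.72 with an estimated correlation). Female-biased liver genes had a median of 0.64 (adjusted p = 0.000667; adjusted p = 0.659 with an estimated correlation), with Acot3 at 0.64 and Cyp2b9 at 2.19, and -0.004 without them (adjusted p = 0.81). Male-biased liver genes had a median of -0.83 (adjusted p = 0.0297; adjusted p = 0.659 with an estimated correlation), with Mup21 at -1.48 and Cyp2u1 at -0.77, and 0.04 without them (adjusted p = 0.676). In these 5 lists called as labelled, no single member passed limma's test over all genes or adjusted over the list alone; 1113 of all genes had an unadjusted p under 0.05.

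Jnk2 KO differed from WT in 82 genes, 33 up and 49 down. Genes of the acute phase response were among those that rose most, including Mt2, a metal-binding metallothionein (4.54, SE 0.88), Saa2, a serum amyloid A gene (3.10, SE 0.50), and Steap4, a metalloreductase (1.91, SE 0.22). Gdpd3, a lysophospholipase D gene, rose by 3.55 (SE 0.27, adjusted p = 3.45e-05), and Abcb1b, a P-glycoprotein drug efflux pump, by 3.05 (SE 0.34, adjusted p = 0.00128). BC018473, Abhd1, Tmc5, Nrg4 and Atp11a rose by 2.06 to 3.09. Besides Mapk9 (-4.57, SE 0.16), Clec2h (-2.53), Sugct (-2.18) and Csad, an enzyme of taurine synthesis (-1.87), fell most, followed by Etnppl, Kcnk10, Sgk2, Fam89a, Cd59a and Gsap at -1.17 to -1.05. Without the 2 doubted arrays 248 genes changed, 136 up and 112 down, and 76 of them were among the 82. Those that rose most then also included the metallothionein gene Mt1 (19.7 fold, log2 SE 0.58), Lcn2 (3.66, SE 0.68), which sequesters bacterial siderophores, the neutrophil chemokine Cxcl1 (3.34, SE 0.42), Saa1 (3.15, SE 0.58) and Rgs16 (2.96, SE 0.62). Those that fell most included Osgin1, Tsc22d1, Sucnr1, Slc15a5, Fbxo21 and Rdh9 at -1.74 to -1.22.

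Of the 23 acute phase genes, 4 rose in Jnk2 KO over all genes tested and 11 adjusted over the list alone, with Fga, a fibrinogen chain, at 1.06 (SE 0.17). The median was 0.62 (camera adjusted p = 1.99e-17; adjusted p = 0.216 with an estimated correlation). The median of the 19 bile acid synthesis and transport genes was -0.44 (adjusted p = 5.9e-06; adjusted p = 0.216 with an estimated correlation). Adjusted over the list alone 7 of them fell, and 3 without the doubted arrays, with the uptake transporters Slco1a4 at -2.22 (adjusted p = 0.0969 over all genes) and Slco1b2 at -0.57 (adjusted p = 0.124). The median of the 23 drug metabolism genes was -0.41 (adjusted p = 0.003; adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone 8 of them fell, with the nuclear receptor gene Nr1i3 at -0.80 and Cyp2c29 at -0.63. Without the doubted arrays 3 fell and 1 rose, and the median was -0.30 (adjusted p = 0.0432; adjusted p = 0.591 with an estimated correlation). Fatty acid synthesis and lipid storage genes had a median of 0.32 (adjusted p = 5.9e-06; adjusted p = 0.216 with an estimated correlation). Adjusted over the list alone 4 of 23 rose, with Acaca, the gene of acetyl-CoA carboxylase, at 0.89 (adjusted p = 0.0583) and Elovl6 at 0.69. When the doubted arrays were left out Lpin1 (2.33, SE 0.45) and the lipid droplet gene Plin4 (0.93, SE 0.15) rose. Cholesterol synthesis genes had a median of -0.21 (adjusted p = 0.0137; adjusted p = 0.553 with an estimated correlation), with Insig1 at -0.70 and Stard4 at -0.57. Interferon-stimulated genes had a median of 0.37 (adjusted p = 5.9e-06; adjusted p = 0.522 with an estimated correlation), with Mx2 at 0.85 (adjusted p = 0.0534). The AP-1 and immediate early list had one of 0.30 (adjusted p = 0.0014; adjusted p = 0.522 with an estimated correlation) and 0.15 without the doubted arrays (adjusted p = 0.00835; adjusted p = 0.591 with an estimated correlation), with the phosphatase gene Dusp1 at 1.53 (adjusted p = 0.055) and Btg2 at 1.66 (adjusted p = 0.0604) as labelled. Monocyte and macrophage markers had a median of 0.61 (adjusted p = 2.48e-06; adjusted p = 0.522 with an estimated correlation) and 0.12 without the doubted arrays (adjusted p = 0.0548), with Cd14 at 0.93 as labelled. Extracellular matrix markers had one of 0.40 (adjusted p = 4.98e-05; adjusted p = 0.553 with an estimated correlation) and -0.09 without them (adjusted p = 0.594), with Fn1 at 0.28 as labelled. The cell cycle list had a median of 0.38 (adjusted p = 0.00017; adjusted p = 0.553 with an estimated correlation) and 0.14 without the doubted arrays (adjusted p = 0.0208; adjusted p = 0.755 with an estimated correlation), with Ccne1 at 0.38 and Rrm2 at 0.98 as labelled. The count of 82 fell to 24 without Jnk2 KO replicate 2 and to 16, 31 and 26 without WT replicates 1, 2 and 3. It was 157 with the sex term, all 82 among them, 161 without the 3 arrays of the female pattern, and 27 with only the arrays compared.

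The single knockouts were compared directly, and 26 genes differed, 9 higher and 17 lower in Jnk1 KO than in Jnk2 KO. Mapk9 (4.63, SE 0.16), Mme (3.65, SE 0.32) and Sucnr1, the succinate receptor gene (2.37, SE 0.41), were higher in Jnk1 KO, and Akr1c19, Gsap, Fam89a, Rps23rg1, Mmd and Fbxo36 by 0.47 to 1.03. Gdpd3 (-3.83, SE 0.27), BC018473 (-3.06, SE 0.37), Saa2 (-2.90, SE 0.50), Abcb1b (-2.87, SE 0.34), Abhd1 (-2.49, SE 0.23) and Igfbp1, a binding protein of insulin-like growth factors (-2.19, SE 0.38), were lower in Jnk1 KO, as were Atp11a, Rps3a1, Steap4 and Pik3c2g at -1.84 to -1.49. Of the 23 acute phase genes, 3 were lower in Jnk1 KO over all genes and 14 adjusted over the list alone, among them Fga (-1.09, SE 0.17). The median was -0.53 (camera adjusted p = 6.77e-22; adjusted p = 0.211 with an estimated correlation), and -0.86 without the doubted arrays (adjusted p = 8.5e-23; adjusted p = 0.302 with an estimated correlation). Bile acid genes had a median of 0.24 (adjusted p = 0.000315; adjusted p = 0.469 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.53 (adjusted p = 0.383). Drug metabolism genes had one of 0.33 (adjusted p = 0.000315; adjusted p = 0.566 with an estimated correlation), with Cyp2c50 at 0.59 (adjusted p = 0.319). In this list the mean went from 0.31 to 0.14 without the doubted arrays, and the median to 0.30 (adjusted p = 0.0237; adjusted p = 0.662 with an estimated correlation). The AP-1 list had a median of -0.20 (adjusted p = 0.00299; adjusted p = 0.613 with an estimated correlation), with Dusp1 at -1.57 (adjusted p = 0.0935), and of -0.32 without those arrays (adjusted p = 0.000176; adjusted p = 0.458 with an estimated correlation). The fatty acid synthesis list had one of -0.27 (adjusted p = 0.000315; adjusted p = 0.469 with an estimated correlation) and -0.031 without the doubted arrays (adjusted p = 0.184), with Acaca at -0.73 as labelled. In the fit without the 2 doubted arrays 119 genes differed, 27 higher and 92 lower in Jnk1 KO. The differences in Mt2 (-6.35, SE 0.65), Mt1 (-4.93, SE 0.64), Lcn2 (-3.86, SE 0.74), Cxcl1 (-3.59, SE 0.46), Sugct (2.59, SE 0.39), Slc15a5, Slc13a2, H1f2, Grb7 and Gas1 (1.00 to 1.86) also passed. The count of 26 was 69 without the array labelled Jnk1 KO replicate 1, 10 without Jnk1 KO replicate 2 and 17 without Jnk1 KO replicate 3. It was 11 and 13 without Jnk2 KO replicates 1 and 2, and 104 without the array labelled Jnk2 KO replicate 3. The sex term gave 37, the fit without the 3 arrays of the female pattern 57, and the fit to only the arrays compared 4.

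**Figure D2:**
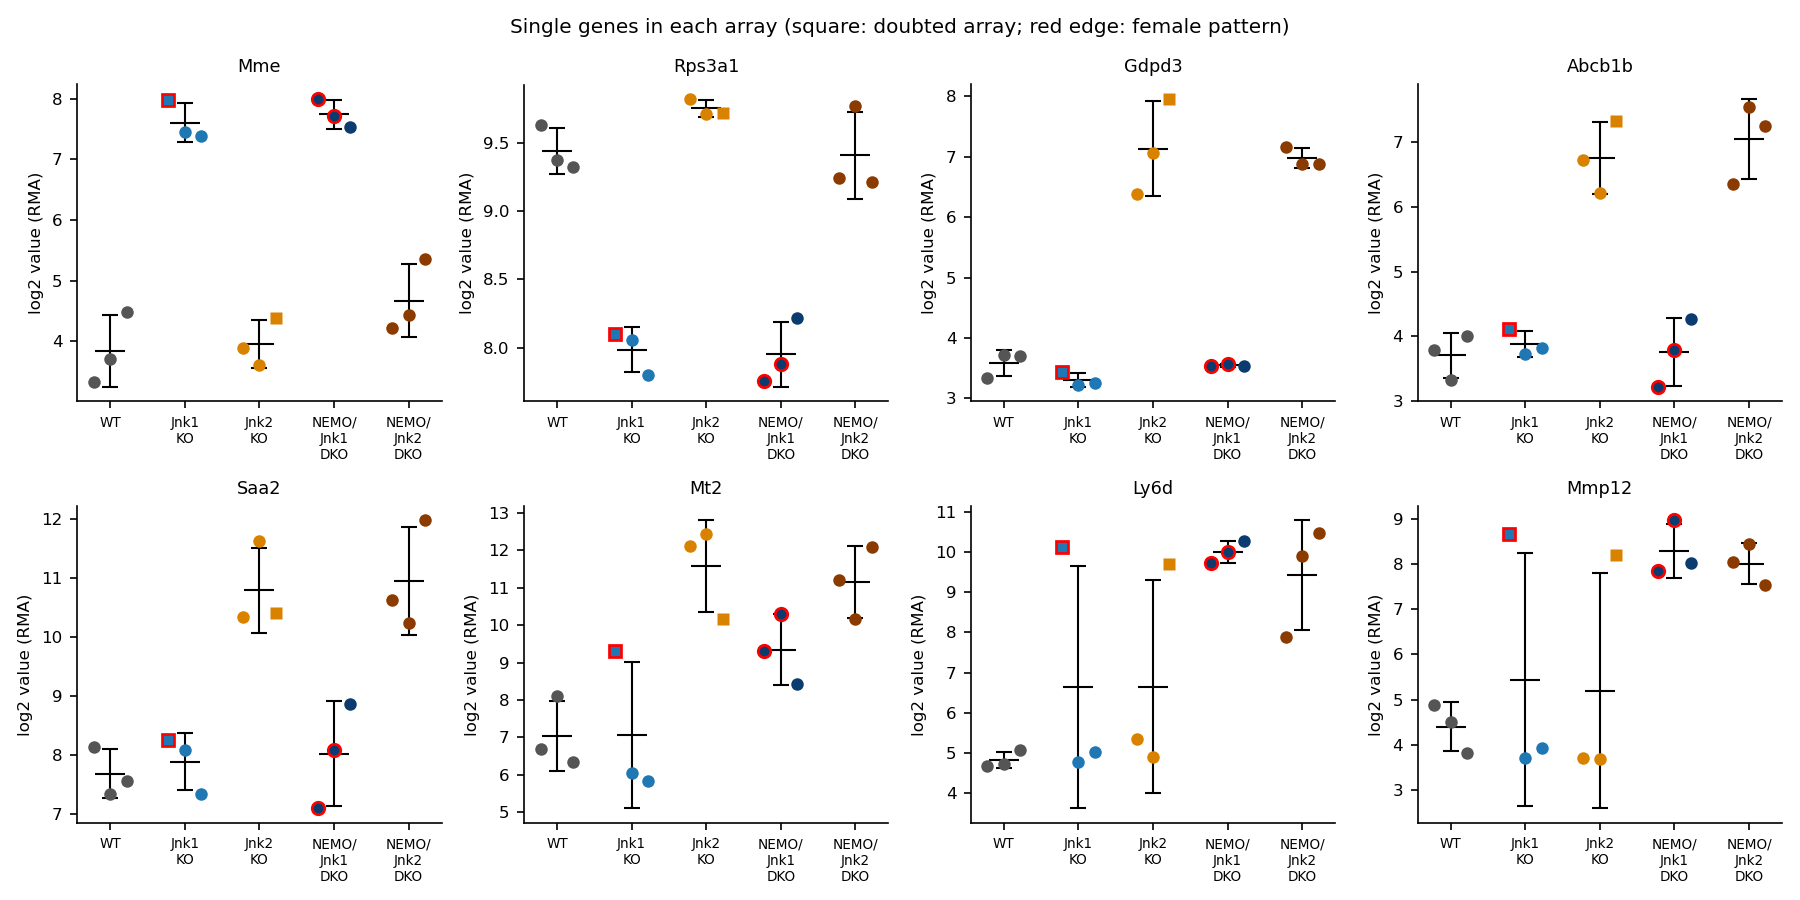
Log2 expression (RMA) of 8 genes in each array, by group, with the mean and SD of 3 arrays. Squares mark the 2 doubted arrays and red edges the 3 arrays with the female pattern. Mme read 7.39 or more in every Jnk1-null array and 5.35 or less elsewhere, and Gdpd3 6.39 or more in every Jnk2-null array and 3.72 or less elsewhere. Ly6d and Mmp12 in the doubted arrays lay at the level of the double knockouts.

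The added loss of NEMO in hepatocytes was read on the Jnk1-null background by comparing NEMO/Jnk1 DKO with Jnk1 KO. As labelled, limma called 0 of 19938 genes (908 at an unadjusted p under 0.05), and without the 2 doubted arrays it called 1033, 808 up and 225 down. In that setting Ly6d (5.11, SE 0.52), Mmp12 (4.45, SE 0.34), D17H6S56E-5 (4.43, SE 0.34), Sprr1a, a squamous envelope protein gene (3.97, SE 0.31), and Mtmr11 (3.58, SE 0.21) were among the genes that rose most. Mt2 (3.41, SE 0.60) and the female-biased Cyp2b9 (5.40, SE 1.03), Slc22a27, Cyp2a22 and Cyp3a16 (3.04 to 3.39) rose as well. Hsd3b5 (-5.50, SE 1.24), Elovl3 (-5.37, SE 1.10) and Cyp7b1 (-3.05, SE 0.69), all male-biased in mouse liver, and Serpina12, the adipokine gene vaspin (-2.96, SE 0.41), fell most, followed by Ces4a, Susd4, Mup21, Ttc39c, Slc15a5 and Adgrf1 at -2.25 to -1.67. Ikbkg fell by 0.62 (SE 0.16, adjusted p = 0.0396), and as labelled it was at -0.48 (SE 0.22, adjusted p = 0.962). The Jnk1 KO array left out was also marked by its low Ikbkg, so this is no independent test. With the doubted arrays left out and the sex term added, the NEMO/Jnk1 DKO estimates rest on replicate 3 alone, so only effect sizes are given. Among the 20 genes named before Ikbkg, Ly6d stood at 5.37, Mmp12 at 4.20, D17H6S56E-5 at 4.83 and Sprr1a at 4.01. Mtmr11 stood at 3.43, Serpina12 at -2.34 and Ces4a at -2.21. Cyp2b9 (2.72), Hsd3b5 (-1.96), Elovl3 (-2.14) and Mt2 (2.49) were smaller in size than without the term, as was Ikbkg (-0.33).

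Without the 2 doubted arrays, 3 lists were higher in NEMO/Jnk1 DKO than in Jnk1 KO also with an estimated correlation. Of the 28 extracellular matrix and stellate cell markers, 19 rose, and 23 adjusted over the list alone, among them the collagen genes Col3a1 (2.24, SE 0.27), Col1a1 (2.13, SE 0.24) and Col1a2 (1.93, SE 0.26) and the proteoglycan lumican, Lum (2.38, SE 0.20). The median was 1.10 (camera adjusted p = 4.71e-28; adjusted p = 0.000871 with an estimated correlation). Of the 22 monocyte and macrophage markers, 15 rose, and 20 adjusted over the list alone, among them Gpnmb (2.50, SE 0.18), Clec7a (2.40, SE 0.23) and Cd68 (1.61, SE 0.18). The median was 1.10 (adjusted p = 9.26e-24; adjusted p = 0.0317 with an estimated correlation). Of the 16 fetal liver and liver tumour markers, 8 rose, and 9 adjusted over the list alone, among them Anxa2 (2.50, SE 0.16), Cd63 (2.21, SE 0.21) and Scd2 (1.99, SE 0.51). The median was 0.97 (adjusted p = 1.24e-10; adjusted p = 0.0016 with an estimated correlation). Of the 33 cell cycle genes, 23 rose, and 27 adjusted over the list alone, among them Ccnd1, the gene of cyclin D1 (3.02, SE 0.33), and the mitotic genes Kif20a (2.44, SE 0.30), Plk1 (2.32, SE 0.31) and Tpx2 (2.29, SE 0.23). The median was 1.05 (adjusted p = 5.17e-27; adjusted p = 0.0716 with an estimated correlation). As labelled, the medians of these 4 lists were 0.57 (adjusted p = 1.92e-10; adjusted p = 0.258 with an estimated correlation), 0.66 (adjusted p = 2.71e-10; adjusted p = 0.249 with an estimated correlation), 0.69 (adjusted p = 2.65e-05; adjusted p = 0.249 with an estimated correlation) and 0.53 (adjusted p = 5.69e-06; adjusted p = 0.473 with an estimated correlation).

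Of the 6 MHC class II genes, which present antigen to T cells, 5 rose in NEMO/Jnk1 DKO without the doubted arrays, among them H2-Eb1 (1.88, SE 0.30) and Cd74 (1.68, SE 0.31). The median was 1.67 (camera adjusted p = 1.72e-07; adjusted p = 0.0928 with an estimated correlation). Of the 16 p53 target and DNA damage genes 4 rose, and 7 adjusted over the list alone, including Btg2 (1.92, SE 0.22), Eda2r (1.06, SE 0.26) and Phlda3 (0.77, SE 0.19). The median was 0.39 (adjusted p = 1.76e-06; adjusted p = 0.0928 with an estimated correlation). Of the 17 NRF2 target and oxidative stress genes 8 rose and 1 fell, and 11 and 2 adjusted over the list alone. Nqo1 (1.83, SE 0.29) and the heme oxygenase gene Hmox1 (1.54, SE 0.25) rose. The median was 0.48 (adjusted p = 1.44e-08; adjusted p = 0.0623 with an estimated correlation). Of the 17 AP-1 and immediate early genes 4 rose, and 7 adjusted over the list alone, including Atf3 (2.15, SE 0.24), Jun (2.06, SE 0.34) and Klf6 (1.54, SE 0.18). The median was 0.36 (adjusted p = 1.76e-06; adjusted p = 0.117 with an estimated correlation). In the cholesterol synthesis list 1 of 17 genes rose, Lss (0.82, SE 0.19), and 4 adjusted over the list alone. The median was 0.25 (adjusted p = 4.63e-05; adjusted p = 0.367 with an estimated correlation), and with the sex term the median was 0.08. Of the 15 male-biased genes 6 fell, and 14 adjusted over the list alone (median -1.98; adjusted p = 3.39e-12; adjusted p = 0.102 with an estimated correlation). Of the 13 female-biased genes 4 rose, including Ntrk2 (1.54, SE 0.18), and 10 adjusted over the list alone (median 1.54; adjusted p = 9.92e-08; adjusted p = 0.0928 with an estimated correlation). In this comparison 2 of the 3 NEMO/Jnk1 DKO arrays carried the female pattern, and with the sex term the last 2 medians were -0.65 and 0.31.

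On the Jnk2-null background, NEMO/Jnk2 DKO was compared with Jnk2 KO. As labelled limma called 1 gene, Prxl2b, a prostaglandin synthase gene (0.95, SE 0.12, adjusted p = 0.0209), with 1578 genes at an unadjusted p under 0.05. When the 2 doubted arrays were left out it called 1167, 773 up and 394 down. In that setting Sprr1a (4.37, SE 0.31), Mmp12 (4.31, SE 0.34), Ly6d (4.31, SE 0.52), D17H6S56E-5 (3.82, SE 0.34), Lum (2.96, SE 0.20), Fgl2 (2.83, SE 0.48) and Gpnmb (2.79, SE 0.18) rose most, followed by Sparcl1, S100a11 and Ect2 (2.45 to 2.66). BC018473 (-2.81, SE 0.41), the haemoglobin scavenger receptor gene Cd163 (-2.78, SE 0.23), Cxcl1 (-2.55, SE 0.42), Rgs16 (-2.54, SE 0.62), Adgrf1 (-2.49, SE 0.35) and Serpina12 (-2.28, SE 0.41) fell most, followed by Lpin1, Cyp2c37, Slco1a4 and Pfkfb3 at -2.15 to -1.79. BC018473 lies on the chromosome of Mapk9. As labelled it was at -2.63 (limma adjusted p = 0.0558), and Cd163 was at -1.68 (adjusted p = 0.602). Ikbkg fell by 0.74 (SE 0.16, adjusted p = 0.0149), and as labelled it was at -0.45 (SE 0.22, adjusted p = 0.654). The Jnk2 KO array left out was also marked by its low Ikbkg, so this is no independent test. The sex term, with no female pattern in these groups, left 1148 calls.

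Without the 2 doubted arrays, 16 of the 28 extracellular matrix and stellate cell markers rose in NEMO/Jnk2 DKO, and 19 adjusted over the list alone, including Col1a1 (2.29, SE 0.24), Col1a2 (2.08, SE 0.26) and Col3a1 (1.86, SE 0.27). The median was 0.87 (camera adjusted p = 1.23e-21; adjusted p = 0.00121 with an estimated correlation). Of the 22 monocyte and macrophage markers 15 rose, and 18 adjusted over the list alone, including Clec7a (2.15, SE 0.23) and the perforin-like Mpeg1 (1.69, SE 0.23). The median was 1.10 (adjusted p = 9.81e-22; adjusted p = 0.0402 with an estimated correlation). Of the 16 fetal liver and liver tumour markers 8 rose, and 10 adjusted over the list alone, including Scd2 (2.34, SE 0.51), Anxa2 (2.34, SE 0.16) and Cd63 (2.15, SE 0.21). The median was 0.94 (adjusted p = 9.67e-13; adjusted p = 0.00121 with an estimated correlation). Of the 33 cell cycle genes 24 rose, and 29 adjusted over the list alone, including Ccna2 (2.24, SE 0.28), Mcm6 (2.23, SE 0.52), Kif20a (2.21, SE 0.30) and Plk1 (2.01, SE 0.31). The median was 1.16 (adjusted p = 5.93e-29; adjusted p = 0.0704 with an estimated correlation). All 6 MHC class II genes rose, including H2-Eb1 (2.34, SE 0.30) and H2-Ab1 (2.29, SE 0.29). The median was 2.00 (adjusted p = 6.98e-11; adjusted p = 0.0704 with an estimated correlation). Of the 16 p53 target genes 6 rose, including Eda2r (1.40, SE 0.26), Plk2 (1.21, SE 0.22) and Phlda3 (1.06, SE 0.19). The median was 0.29 (adjusted p = 5.71e-05; adjusted p = 0.161 with an estimated correlation). Of the 17 NRF2 target genes 6 rose, and 9 adjusted over the list alone, including Gstm3 (1.75, SE 0.28) and Ephx1 (0.84, SE 0.15). The median was 0.38 (adjusted p = 1.89e-07; adjusted p = 0.0754 with an estimated correlation).

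In the growth hormone and insulin-like growth factor axis 2 of 12 genes fell in NEMO/Jnk2 DKO without the doubted arrays, Igfbp1 (-1.09, SE 0.23) and the growth hormone receptor gene Ghr (-0.50, SE 0.12), and 6 adjusted over the list alone. The median was -0.58 (camera adjusted p = 0.00012; adjusted p = 0.0942 with an estimated correlation). In the urea cycle and amino acid catabolism list 2 of 15 genes fell, the tyrosine aminotransferase gene Tat (-0.65, SE 0.17) and the argininosuccinate lyase gene Asl (-0.54, SE 0.13), and 8 adjusted over the list alone. The median was -0.35 (adjusted p = 4.52e-06; adjusted p = 0.174 with an estimated correlation). As labelled, the calls of all these lists on the Jnk2-null background were lost with an estimated correlation (adjusted p = 0.406 for the growth hormone axis, adjusted p = 0.695 for the extracellular matrix list and adjusted p = 0.535 for the others). The count of 1 gene was 119 without the array labelled Jnk2 KO replicate 3 alone, 5 and 2 without Jnk2 KO replicate 2 and NEMO/Jnk2 DKO replicate 3, and 0 by limma without NEMO/Jnk2 DKO replicate 1 and with only the arrays compared. Prxl2b lost its call in these last 2 fits (adjusted p = 0.238 and 0.345). It also lost it without Jnk2 KO replicate 1 (adjusted p = 0.106) and without NEMO/Jnk2 DKO replicate 2 (adjusted p = 0.0702), where the 1 gene called was another.

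**Figure D3:**
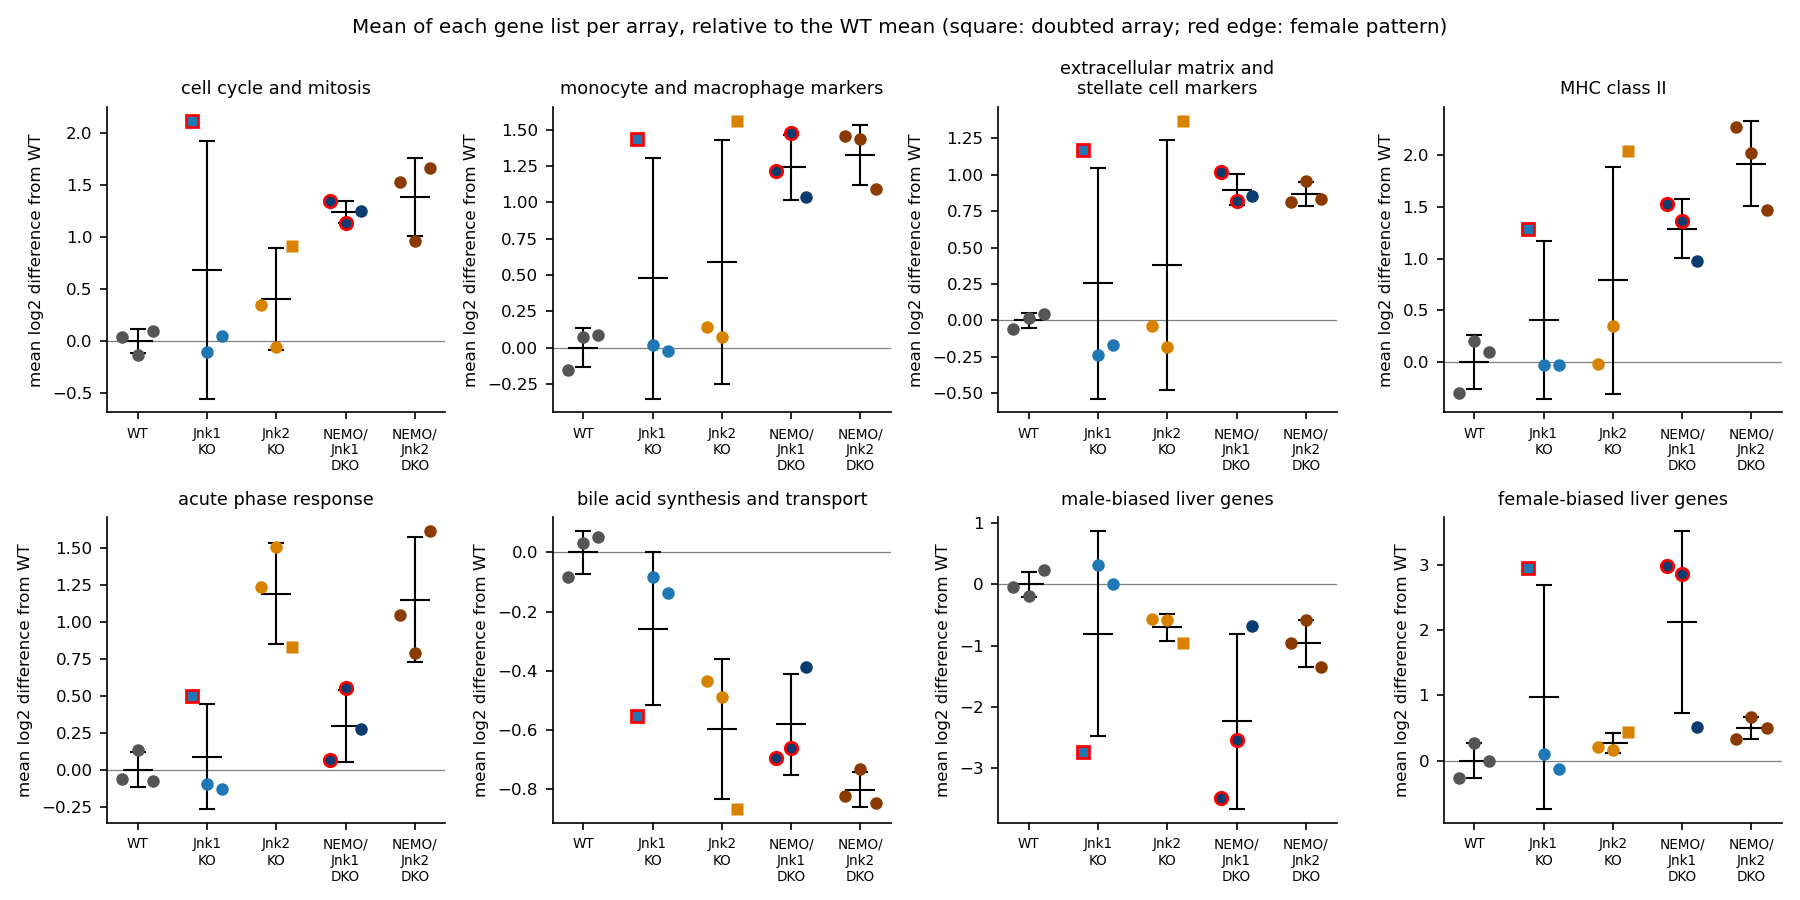
Mean log2 difference from the WT mean of 8 gene lists in each array, by group, with the mean and SD of 3 arrays. Squares mark the 2 doubted arrays and red edges the 3 arrays with the female pattern. In the cell cycle, macrophage, matrix and MHC class II lists the doubted arrays lie at 0.92 or more and the other NEMO-intact arrays at 0.35 or less. The female-biased list lies at 2.86 to 2.98 in the 3 arrays with the female pattern and at 0.67 or less elsewhere.

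The genes called in the 2 NEMO comparisons, which share no arrays but share the spread estimate of each gene, overlapped. That sharing can favour the same genes in both, so the overlap of independent lists is a reference and not a test. The doubted arrays were also set aside by the double-knockout pattern itself. With the doubted arrays left out 472 genes rose in both, out of 808 and 773, where independent lists would share 31.3, and 75 fell in both, out of 225 and 394, where independent lists would share 4.45. Igfbp1 (1.76 and -1.09) and Slc25a25 (1.05 and -1.35) rose on the Jnk1-null and fell on the Jnk2-null background. Across genes, which are not independent replicates, Pearson's r between both sets of fold changes was 0.618 without the doubted arrays and 0.502 as labelled. It was 0.584 without the doubted arrays and with the sex term, where NEMO/Jnk1 DKO rests on replicate 3 alone.

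**Figure D4:**
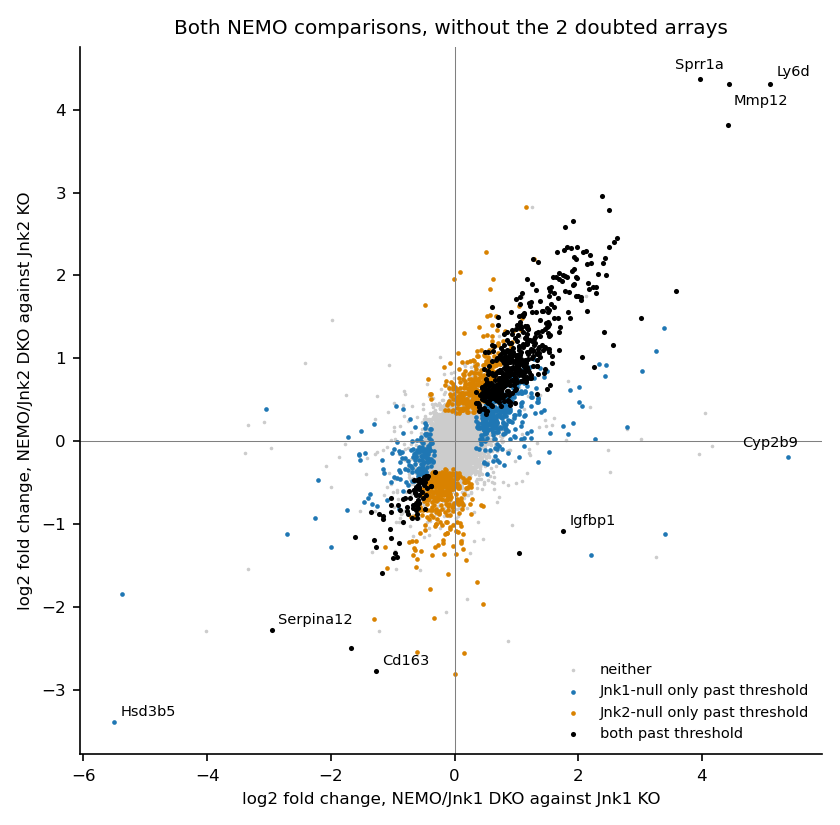
Log2 fold change of each of 19938 genes between NEMO/Jnk1 DKO and Jnk1 KO (horizontal axis) and between NEMO/Jnk2 DKO and Jnk2 KO (vertical axis), without the 2 doubted arrays. Colours mark genes past the threshold of adjusted p under 0.05 in either or both comparisons. Ly6d lies at 5.11 and 4.31, and Igfbp1 rose by 1.76 on one background and lay at -1.09 on the other.

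Whether NEMO loss acted differently on the 2 Jnk backgrounds was tested as the difference of both effects. As labelled limma called 0 genes (548 at an unadjusted p under 0.05). With the doubted arrays left out Igfbp1 (2.84, SE 0.33, adjusted p = 0.019) and Cyp2c54, a cytochrome P450 gene (1.49, SE 0.20, adjusted p = 0.0403), passed, with a more positive NEMO effect on the Jnk1-null background. After adding the sex term, where NEMO/Jnk1 DKO rests on replicate 3 alone, they were at 2.92 and 1.45. Igfbp1 read 8.33 and 8.44 in Jnk1 KO replicates 3 and 2 and 9.75 to 10.5 in NEMO/Jnk1 DKO, but 11.1 and 11.8 in Jnk2 KO replicates 1 and 2 and 10.3 to 10.4 in NEMO/Jnk2 DKO. As labelled, 7 of the 35 lists had a more positive and 2 a more negative NEMO effect on the Jnk1-null background. These were 16 and 2 without the doubted arrays, and 0 by camera with an estimated correlation both as labelled and without those arrays. The AP-1 and immediate early list differed by 0.47 (camera adjusted p = 0.000217; adjusted p = 0.441 with an estimated correlation), with Dusp1 at 1.99 and Fos at 1.26, and by 0.58 without the doubted arrays (adjusted p = 1.23e-05; adjusted p = 0.362 with an estimated correlation). The cholesterol synthesis list differed by 0.40 (adjusted p = 4.7e-10; adjusted p = 0.441 with an estimated correlation), with Cyp51 at 0.72 and Sqle at 0.68. Without the doubted arrays it differed by 0.19 (adjusted p = 0.00149; adjusted p = 0.532 with an estimated correlation), and with the sex term added by 0.012.

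The series title raises the role of Jnk1, and NEMO/Jnk1 DKO was compared with NEMO/Jnk2 DKO, in which 21 genes differed, 9 higher and 12 lower in NEMO/Jnk1 DKO. Mapk9 (4.90, SE 0.16), the organic anion transporter Slco1a4 (3.14, SE 0.54), Mme (3.07, SE 0.32), Cyp2c54 (1.77, SE 0.28) and Cyp2c50 (1.46, SE 0.17) were higher in NEMO/Jnk1 DKO, as were Etnppl, Ces1d, Aldh4a1 and the paraoxonase gene Pon1 (0.55 to 1.34). Gdpd3 (-3.43, SE 0.27), Abcb1b (-3.29, SE 0.34), Tmc5 (-3.27, SE 0.43), Saa2 (-2.92, SE 0.50) and Abhd1 (-2.17, SE 0.23) were lower in NEMO/Jnk1 DKO, as were Ift57, Rps3a1, Atp11a, Cltb and Prxl2b at -1.49 to -0.93. Without the doubted arrays, which are not in these groups but enter the estimate of the spread, 64 genes differed, 36 higher and 28 lower. They now included Cyp2c37 (2.30), Mug2 (2.25), Akr1c18, Sugct, Sucnr1 and Acss3 (1.64 to 1.92), Saa1 (-3.15), Scara5 (-2.19), Obp2a and Asic5 (-1.70 and -1.69). With the sex term added as well, the NEMO/Jnk1 DKO estimates rest on replicate 3 alone, so only effect sizes are given. Slco1a4 (2.52), Saa2 (-2.07), Saa1 (-1.96), Scara5 (-1.64), Acss3 (1.21) and Cyp2c37 (1.65) were then smaller in size, and Sucnr1 (2.32) was larger. Mug2 (2.20), Akr1c18 (1.95), Sugct (1.80), Obp2a (-1.82) and Asic5 (-1.55) changed little. The count of 21 was 9 to 20 with each array left out in turn, 15 with the sex term alone, 3 without the 3 arrays of the female pattern and 97 with array weights.

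NEMO/Jnk1 DKO replicates 1 and 2 carried the female pattern and no NEMO/Jnk2 DKO array did. Over all 35 lists camera called 10 up and 4 down as labelled, and 8 up and 10 down with the sex term alone. The lists below are given without that term unless stated, so sex may enter their values. Of the 23 acute phase genes, 1 was lower in NEMO/Jnk1 DKO than in NEMO/Jnk2 DKO, and 5 adjusted over the list alone. The median was -0.59 (camera adjusted p = 4.18e-19; adjusted p = 0.311 with an estimated correlation). Of the 23 drug metabolism genes 2 were higher, and 7 adjusted over the list alone against 1 lower. The median was 0.23 (adjusted p = 1.47e-06; adjusted p = 0.345 with an estimated correlation). Bile acid genes had a median of 0.20 (adjusted p = 0.000298; adjusted p = 0.345 with an estimated correlation). Urea cycle genes had one of 0.33 (adjusted p = 2.14e-06; adjusted p = 0.345 with an estimated correlation), with Hpd at 0.36 and Oat at 0.90. Fatty acid oxidation genes had one of 0.24 (adjusted p = 2.29e-05; adjusted p = 0.345 with an estimated correlation), with Cyp4a31 at 1.92 (adjusted p = 0.27) and Cyp4a10 at 1.33. MHC class II genes had a median of -0.70 (adjusted p = 0.00444; adjusted p = 0.507 with an estimated correlation), with H2-DMa at -0.66 and H2-Aa at -0.74. Neutrophil markers had one of -0.15 (adjusted p = 0.00468; adjusted p = 0.345 with an estimated correlation), with S100a8 at -0.40. Endothelial markers had a median of 0.21 (adjusted p = 0.00043; adjusted p = 0.345 with an estimated correlation), with Egfl7 at 0.31 and Clec4g at 0.37. Male-biased genes had a median of -0.84 (adjusted p = 1.47e-06; adjusted p = 0.445 with an estimated correlation), with C8a at -0.64, and turned to 0.33 with the sex term (adjusted p = 0.0169). Female-biased genes had a median of 0.92 (adjusted p = 2.14e-06; adjusted p = 0.345 with an estimated correlation), with Sult3a1 at 4.18. Cholesterol synthesis genes had one of 0.35 (adjusted p = 2.52e-07; adjusted p = 0.345 with an estimated correlation), with Sc5d at 0.45. Without the doubted arrays and with the sex term, where NEMO/Jnk1 DKO rests on replicate 3 alone, the last 2 medians were -0.024 and 0.031.

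Both losses together were compared with WT. NEMO/Jnk1 DKO differed in 13 genes, 6 up and 7 down. This count was 3 with the sex term, 5 to 11 with each array left out in turn, and 0 by limma without the 3 arrays of the female pattern (1865 at an unadjusted p under 0.05), but 1293 with only the arrays compared and 1115 with array weights. Mme rose by 3.91 (SE 0.32), the acetylcholine receptor subunit gene Chrna4 by 1.37 (SE 0.19), the ammonium transporter gene Rhbg by 1.19 (SE 0.20), and the death receptor gene Tnfrsf21, H1f3 and the pentose phosphate enzyme gene Pgd by 0.85 to 0.91. Asic5 (-3.08, SE 0.38), Rps3a1 (-1.49, SE 0.16), the natriuretic peptide receptor gene Npr2 (-1.21, SE 0.14), Kcnk10 (-1.13, SE 0.18), Mapk8 (-0.88, SE 0.15) and Pigyl (-0.74, SE 0.12) fell. Leaving out the doubted arrays, which enter here only through the estimate of the spread, 1578 genes were called, 981 up and 597 down. Among those that rose most were Cyp2b9 (5.37), Ly6d (5.18), Cyp2b13 (4.17), Mmp12 (3.87), D17H6S56E-5 (3.76) and Sprr1a (3.72), and among those that fell most Hsd3b5 (-5.58), Elovl3 (-5.50), Serpina4-ps1 (-3.83), Slco1a1 (-3.50), the Y-linked Uty (-3.23) and Serpina12 (-3.12). With the sex term added to that setting 262 genes were called, with Ly6d (5.45), Mmp12 (3.62), D17H6S56E-5 (4.17), Sprr1a (3.76) and Serpina12 (-2.50) among them. The other 7 of these 12 genes lost their calls: Cyp2b9 (2.69, adjusted p = 0.141), Cyp2b13 (0.25, adjusted p = 0.9), Hsd3b5 (-2.03, adjusted p = 0.284), Elovl3 (-2.26, adjusted p = 0.0919), Serpina4-ps1 (-1.80, adjusted p = 0.68), Slco1a1 (adjusted p = 0.79) and Uty (-0.34, adjusted p = 0.472).

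In NEMO/Jnk1 DKO against WT, 21 of 33 cell cycle genes rose adjusted over the list alone as labelled, and 26 over all genes without the doubted arrays, including Ccnd1 (2.84, SE 0.30) and Kif20a (2.31, SE 0.27). The median was 1.09 (camera adjusted p = 1.19e-17; adjusted p = 0.215 with an estimated correlation). Of the 22 monocyte and macrophage markers 16 rose adjusted over the list alone as labelled, and 19 over all genes without the doubted arrays, including Clec7a (2.29, SE 0.20) and Gpnmb (2.26, SE 0.16). The median was 1.13 (adjusted p = 1.47e-15; adjusted p = 0.215 with an estimated correlation). When the doubted arrays were left out, 20 of the 28 extracellular matrix markers rose, including Lum (2.21, SE 0.18) and Mmp2 (1.38, SE 0.20), and 8 of the 16 fetal liver and tumour markers, including Anxa2 (2.42, SE 0.14) and Lgals1 (2.04, SE 0.15). So did 5 of the 6 MHC class II genes, including Cd74 (1.73, SE 0.28), and 5 of the 19 interferon-stimulated genes, including Usp18 (1.28, SE 0.19). As labelled, 2 extracellular matrix, 8 fetal liver and tumour and 4 MHC class II genes rose adjusted over the list alone. The adjusted p of these 3 lists was 4.56e-12, 1.58e-06 and 4.95e-05 (adjusted p = 0.215 with an estimated correlation for each). That of the interferon-stimulated genes was 8.86e-07 (adjusted p = 0.228 with an estimated correlation). Without the doubted arrays, camera with an estimated correlation called 3 of the 35 lists in this comparison, all up, against 0 as labelled. NRF2 target genes had a median of 0.44 (adjusted p = 3.01e-06; adjusted p = 0.215 with an estimated correlation), with 7 up and 1 down in limma without the doubted arrays, Nqo1 (1.72, SE 0.26) and Gstp1 (-0.96, SE 0.23) among them. Bile acid genes had a median of -0.47 (adjusted p = 0.0025; adjusted p = 0.215 with an estimated correlation), with 8 down and 1 up in that setting, including the sterol hydroxylase gene Cyp8b1 (-1.24, SE 0.22). Male-biased genes had a median of -1.90 and female-biased genes one of 1.44 (adjusted p = 6.54e-08 and 2.54e-07; adjusted p = 0.215 with an estimated correlation for both). Without the doubted arrays and with the sex term, where NEMO/Jnk1 DKO rests on replicate 3 alone, these were -0.46 and 0.25.

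NEMO/Jnk2 DKO differed from WT in 525 genes, 174 up and 351 down. Sprr1a (4.34, SE 1.00), Mt2 (4.12, SE 0.88), Cyp2c39 (4.09, SE 0.86), Lcn2 (4.08, SE 0.80), Tmc5 (3.54, SE 0.43), Gdpd3 (3.40, SE 0.27), Abcb1b (3.35, SE 0.34) and Saa2 (3.26, SE 0.50) rose most, followed by the acute phase gene Orm2 and the annexin gene Anxa2 (3.05 and 2.90). Mapk9 (-4.83, SE 0.16), Slco1a4 (-3.65, SE 0.54), Sugct (-2.72, SE 0.42), Cyp2c37 (-2.43, SE 0.42), Clec2h (-2.39, SE 0.28) and Mug2 (-2.37, SE 0.42) fell most, followed by Sucnr1, Cyp2c54, Pcp4l1 and Car1 at -2.12 to -1.91. In the fit without the doubted arrays 2116 genes were called, 1147 up and 969 down. Ly6d (4.61, SE 0.46), D17H6S56E-5 (4.28, SE 0.30) and Mmp12 (3.60, SE 0.30) were then among those that rose most, and Hsd3b5 (-4.19, SE 1.11), Adh6-ps1 (-3.05, SE 0.67) and Serpina12 (-2.70, SE 0.36) among those that fell most. The count of 525 was 56, 160 and 167 without NEMO/Jnk2 DKO replicates 1, 2 and 3 and 139, 62 and 146 without WT replicates 1, 2 and 3. It was 1035 with the sex term, 1171 without the 3 arrays of the female pattern, 1919 with only the arrays compared and 1813 with array weights. No array of these groups has the female pattern, so the sex term altered only the estimate of the spread.

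Of the 23 acute phase genes 8 rose in NEMO/Jnk2 DKO against WT, and 13 rose and 1 fell adjusted over the list alone. The median was 0.36 (camera adjusted p = 7.65e-12; adjusted p = 0.233 with an estimated correlation). Of the 6 MHC class II genes 4 rose, and 6 adjusted over the list alone, including H2-Ab1 (2.50, SE 0.61), H2-Aa (2.47, SE 0.56) and Cd74 (2.37, SE 0.56). The median was 2.37 (adjusted p = 1.09e-07; adjusted p = 0.233 with an estimated correlation). Of the 19 interferon-stimulated genes 3 rose, and 7 adjusted over the list alone, Ifi27l2a (1.81, SE 0.45), Usp18 (1.51, SE 0.37) and Mx2 (0.73, SE 0.17) among them. The median was 0.58 (adjusted p = 3.47e-08; adjusted p = 0.264 with an estimated correlation). Of the 33 cell cycle genes Rrm2 (1.54, SE 0.36) rose, and 32 adjusted over the list alone. The median was 1.31 (adjusted p = 1.09e-20; adjusted p = 0.264 with an estimated correlation, and adjusted p = 0.045 without the doubted arrays). Of the 22 monocyte and macrophage markers Cd9 (1.54, SE 0.33) and Adgre1 (1.17, SE 0.26) rose, and 19 adjusted over the list alone. The median was 1.29 (adjusted p = 2.47e-15; adjusted p = 0.233 with an estimated correlation, and adjusted p = 0.0176 without the doubted arrays). Without those arrays 20 of the 28 extracellular matrix markers rose, including Lum (2.30, SE 0.18) and Col6a3 (1.71, SE 0.12), and 9 of the 16 fetal liver and tumour markers, including Anxa5 (1.71, SE 0.14). For both lists adjusted p = 0.00115 with an estimated correlation, against 0.264 and 0.233 as labelled. Of the 19 bile acid genes 6 fell, and 11 adjusted over the list alone, including Slco1a4, Cyp8b1 (-1.65, SE 0.37), the fibroblast growth factor co-receptor gene Klb (-1.20, SE 0.27) and Slco1b2 (-0.85, SE 0.15). The median was -0.63 (adjusted p = 2.61e-07; adjusted p = 0.233 with an estimated correlation, and adjusted p = 0.0176 without the doubted arrays). Of the 23 drug metabolism genes 5 fell and Cyp2c39 rose, and 8 and 1 adjusted over the list alone, including Cyp2c50 (-1.40, SE 0.17). The median was -0.34 (adjusted p = 0.00061; adjusted p = 0.264 with an estimated correlation). Of the 15 urea cycle and amino acid catabolism genes Asl (-0.65, SE 0.14) fell, and 6 adjusted over the list alone. The median was -0.37 (adjusted p = 0.000104; adjusted p = 0.264 with an estimated correlation).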

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

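The tests without the 2 doubted arrays (those labelled Jnk1 KO replicate 1 and Jnk2 KO replicate 3) and with the sex term were chosen only after the results were seen. With 3 arrays per group, no array was tested as an outlier within its group.

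What drew attention here was a difference between groups: as labelled, the NEMO effect on 9 gene lists differed between the Jnk1-null and the Jnk2-null background by camera's test of the difference itself. It was more negative on the Jnk1-null background for the cell cycle list (-0.466, adjusted p = 0.000352) and the male-biased genes (-0.915, adjusted p = 0.000192). It was more positive for endothelial markers (0.212, adjusted p = 0.000626), AP-1 and immediate early genes (0.473, adjusted p = 0.000217), NF-kB target genes (0.153, adjusted p = 0.0286) and the growth hormone and insulin-like growth factor axis (0.225, adjusted p = 0.00503). The same held for fatty acid synthesis (0.331, adjusted p = 8.34e-05), cholesterol synthesis (0.400, adjusted p = 4.7e-10) and the urea cycle (0.171, adjusted p = 0.0154). With an estimated correlation none of the 9 passed (adjusted p = 0.441 to 0.875). Leaving out the doubted arrays raised the lists called to 18, 16 more positive and 2 more negative, none of which passed with an estimated correlation (adjusted p = 0.362 to 0.576). In that setting the cell cycle difference was 0.006 (adjusted p = 0.787), and the male-biased difference -1.788 (adjusted p = 3.48e-10), but -0.285 with the sex term added. For single genes, Igfbp1 (2.844, SE 0.33, adjusted p = 0.019) and Cyp2c54 (1.494, SE 0.20, adjusted p = 0.0403) passed limma's test of the difference without the doubted arrays. With the sex term added, where NEMO/Jnk1 DKO rests on replicate 3 alone, they were at 2.92 and 1.445.

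A signal also lay in data outside the comparisons of the report. Among the 13767 probe sets with no symbol or several, 24 passed limma's test between Jnk2 KO and WT (18 up, 6 down), 10 between Jnk1 KO and Jnk2 KO (2 up, 8 down), 1 between NEMO/Jnk1 DKO and WT (down) and 24 between NEMO/Jnk2 DKO and WT (12 up, 12 down).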

How the results depend on the processing

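The tests without the 2 doubted arrays, with the sex term and without the 3 arrays of the female pattern were chosen only after the results were seen. Of 467 results for single genes under every setting, 6735 values kept their direction and their side of the threshold, 797 were called only under the alternative, and 535 lost their call or, uncalled in both, changed sign. No called gene changed sign. For 88 results of gene lists these were 1191, 15 and 253, and 3 values, of 2 called lists, were called in the opposite direction. A list that changed direction without a call in both fits counts among the 253. The trend with a robust prior, quantile normalization again, the dim filter, the fold minimum, every probe set and the chromosomes of Mapk8 and Mapk9 left out moved no count by more than 1.5 times. Signal near background limits what the arrays show of dim genes, and 3 arrays per group limit the rest.

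When the 2 doubted arrays were left out, the counts became 248 (Jnk2 KO against WT), 119 (Jnk1 KO against Jnk2 KO), 1033 (NEMO/Jnk1 DKO against Jnk1 KO), 1167 (NEMO/Jnk2 DKO against Jnk2 KO), 64 (NEMO/Jnk1 DKO against NEMO/Jnk2 DKO), 1578 (NEMO/Jnk1 DKO against WT), 2116 (NEMO/Jnk2 DKO against WT) and 2 (difference of the NEMO effects). Of the tests of targeted genes, 5 passed as labelled and 9 without those arrays. Adding the sex term gave 6 (Jnk1 KO against WT), 243 (Jnk2 KO against WT), 111 (Jnk1 KO against Jnk2 KO), 242 (NEMO/Jnk1 DKO against Jnk1 KO), 1148 (NEMO/Jnk2 DKO against Jnk2 KO), 262 (NEMO/Jnk1 DKO against WT) and 2095 (NEMO/Jnk2 DKO against WT), with 8 tests of targeted genes. The median of the extracellular matrix list between Jnk1 KO and WT turned to -0.179 in both settings. The sex term alone gave 157 (Jnk2 KO against WT), 3 (NEMO/Jnk1 DKO against WT) and 1035 (NEMO/Jnk2 DKO against WT), and the male-biased genes between NEMO/Jnk1 DKO and NEMO/Jnk2 DKO turned to 0.333. Without the 3 arrays of the female pattern, which leaves NEMO/Jnk1 DKO 1 array assumed to vary like the others, they were 161 (Jnk2 KO against WT), 57 (Jnk1 KO against Jnk2 KO), 2 (NEMO/Jnk2 DKO against Jnk2 KO), 3 (NEMO/Jnk1 DKO against NEMO/Jnk2 DKO), 0 by limma (NEMO/Jnk1 DKO against WT) and 1171 (NEMO/Jnk2 DKO against WT). For these changes and those below the cause was not tested.

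With only the arrays compared in the fit, limma's counts were 0 (Jnk1 KO against WT), 27 (Jnk2 KO against WT), 4 (Jnk1 KO against Jnk2 KO), 0 (NEMO/Jnk2 DKO against Jnk2 KO), 1293 (NEMO/Jnk1 DKO against WT) and 1919 (NEMO/Jnk2 DKO against WT). With array weights they were 3 (NEMO/Jnk2 DKO against Jnk2 KO), 97 (NEMO/Jnk1 DKO against NEMO/Jnk2 DKO), 1115 (NEMO/Jnk1 DKO against WT) and 1813 (NEMO/Jnk2 DKO against WT), and with centred arrays 2 (NEMO/Jnk2 DKO against Jnk2 KO). For the gene lists 144 calls were made over all comparisons. Over the same 9 comparisons camera with an estimated correlation called 0 and fry 13.

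With each array left out in turn the counts ran from 2 to 3 (Jnk1 KO against WT), 16 to 121 (Jnk2 KO against WT), 10 to 104 (Jnk1 KO against Jnk2 KO), 0 to 263 (NEMO/Jnk1 DKO against Jnk1 KO), 0 to 119 (NEMO/Jnk2 DKO against Jnk2 KO), 9 to 20 (NEMO/Jnk1 DKO against NEMO/Jnk2 DKO), 5 to 11 (NEMO/Jnk1 DKO against WT), 56 to 167 (NEMO/Jnk2 DKO against WT) and 0 to 2 (difference of the NEMO effects). Calls of gene lists ran from 134 to 151 and tests of targeted genes from 4 to 6. The count of 263 came without the array labelled Jnk1 KO replicate 1, and those of 121, 104 and 119 without the array labelled Jnk2 KO replicate 3.

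The labels share replicate numbers between groups but name different mice. The deviations of arrays of the same number correlated between -0.395 and 0.304, over 0.1 in 3 of 24 pairs and in no comparison for all 3, so the arrays were not treated as paired. With the replicate block the counts were 2, 55, 18, 0 by limma, 1, 21, 7 (NEMO/Jnk1 DKO against WT), 263 (NEMO/Jnk2 DKO against WT) and 0, in the order of the comparisons above. The 1 gene of NEMO/Jnk2 DKO against Jnk2 KO was then not Prxl2b (adjusted p = 0.0593).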

Other observations

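All tests on the doubted arrays, the female pattern and the genes that separate the Jnk1-null from the Jnk2-null arrays were chosen only after the results were seen; the splits of the 9 planned comparisons were planned. In the fit without the 2 doubted arrays, 7 of 26 chemokine and cytokine genes rose in NEMO/Jnk1 DKO against Jnk1 KO, and 10 adjusted over the list alone, among them Cxcl14 (1.79), Ccl3 (1.71), Cxcl10 (1.17) and Ccl2 (0.93). The median was 0.28 (camera adjusted p = 1.03e-06; adjusted p = 0.0719 with an estimated correlation). In NEMO/Jnk2 DKO against Jnk2 KO 5 rose and 1 fell, with Cxcl14 at 1.99, Ccl3 at 1.38, Cxcl10 at 1.07 and Cxcl1 at -2.55 (median 0.13, adjusted p = 0.0165; adjusted p = 0.352 with an estimated correlation). Mlkl, the effector of necroptosis, rose by 1.41 and 1.32 in these comparisons, and the death receptor gene Tnfrsf10b by 0.84 and 0.74. The medians of the 19 death receptor, caspase and necroptosis genes were 0.29 (adjusted p = 1.96e-05; adjusted p = 0.0623 with an estimated correlation) and 0.14 (adjusted p = 0.253). Of the 11 Kupffer cell markers Marco (2.33) and Cd5l (1.08) rose and Cd163 (-1.27) fell on the Jnk1-null background (median 0.45, adjusted p = 0.0236; adjusted p = 0.406 with an estimated correlation), and Cd163 fell by 2.78 on the Jnk2-null background (median 0.03, adjusted p = 0.7).

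The 2 doubted arrays carried the pattern of the double knockouts. Against an exchange of labels with a double knockout of the series, the lowest first-component score of the 6 double-knockout arrays was 9.9, above the highest of the other NEMO-intact arrays (-15.5). Partial mixing with double-knockout RNA would place an array between the groups, but both scored above the lowest matching double knockout, the nearer by 4.3. This cannot exclude mixing with RNA of a higher-scoring double knockout. In the array labelled Jnk1 KO replicate 1 Ikbkg was 6.748, within the 6.184 to 6.848 of NEMO/Jnk1 DKO. In the array labelled Jnk2 KO replicate 3 it was 6.243, below the 6.312 to 6.478 of NEMO/Jnk2 DKO. A wrong NEMO genotype label, or a sample from outside the series, remains open: the higher Ikbkg value of the 2 was 6.748, below the lowest of the other NEMO-intact arrays (7.026). A liver injury that also lowers Ikbkg was not tested.

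Of the mice labelled male, 3 had high Xist and low Y-linked genes (the arrays labelled Jnk1 KO replicate 1 and NEMO/Jnk1 DKO replicates 1 and 2). Female and male RNA in equal parts would keep the Y-linked genes within 1 log2 unit of the others, but the gap was 3.811, from a highest mean of 2.98 in the 3 arrays. Female animals fit: their lowest mean shift of the female-biased liver genes was 2.858, against at most 0.666 in the other 12 arrays. NEMO/Jnk1 DKO then holds 2 female and 1 male animals, and sex is partly confounded with its comparisons.

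Across both NEMO states 109 genes differed between the 6 Jnk1-null and the 6 Jnk2-null arrays (65 higher and 44 lower in Jnk1-null), and 223 without the doubted arrays (94 and 129, 95 of the 109 among them), 76 with the sex term (43 and 33, 47 of the 109) and 117 with both (57 and 60, 60 of the 109). Of 100 splits within the NEMO states only the real one, 1, reached 109 (highest other 4). All 3 arrays of the female pattern are Jnk1-null, so sex is partly confounded with this comparison. The splits, and the position tests below, used the fit without the sex term, so they cannot tell sex apart from the Jnk genotype. Apart from Mapk9, the lowest p belonged to Gdpd3 (3.43 ± 0.15 against 7.06 ± 0.52, n = 6 each, and 3.58 ± 0.22 in 3 WT), Abhd1, Mme (7.68 ± 0.26 against 4.32 ± 0.60, 3.83 ± 0.59 in WT) and Rps3a1. DNA of the donor strain linked to the targeted gene cannot be told apart from chance placement by the 7 called genes within 200 tested genes of Mapk8 or Mapk9 (median of random draws 4, permutation p = 0.12). Donor segments elsewhere fit, since 71 pairs of called genes of different name stems lay within 50 tested genes of each other off those chromosomes (median of random draws 25, permutation p = 1e-04, the smallest possible with 10000 draws), against 31 pairs (median 26, permutation p = 0.23) among the 109 genes of lowest p for NEMO loss. A name stem was the first 3 letters of the symbol, so related genes such as Fga and Fgg, both called, have different stems. The random draws picked genes singly. Neighbouring genes under shared regulation could also be called together, so an effect of JNK1 or JNK2 on these genes stays open.

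Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. The real grouping or a larger count was met by 1 of 10 for Jnk1 KO against WT (2 genes, highest other 0), Jnk2 KO against WT (82, 0), NEMO/Jnk1 DKO against NEMO/Jnk2 DKO (21, 0), NEMO/Jnk1 DKO against WT (13, 0) and NEMO/Jnk2 DKO against WT (525, 0). It was met by 2 for Jnk1 KO against Jnk2 KO (26, 65) and NEMO/Jnk2 DKO against Jnk2 KO (1, 4), and by 10 for NEMO/Jnk1 DKO against Jnk1 KO (0 by limma, 140). The 140 genes came from the array labelled Jnk1 KO replicate 1 grouped with NEMO/Jnk1 DKO replicates 1 and 2, the 3 arrays of the female pattern. For the difference of the NEMO effects all 100 of 100 splits gave at least the real 0 by limma, the highest other 708. A real count of 0, as here and for NEMO/Jnk1 DKO against Jnk1 KO, is met by any split, so it does not bear on chance.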
